A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

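Polyadenylated RNA of Saccharomyces cerevisiae was hybridised to 6 two-channel spotted arrays, 3 per genotype, with untreated RNA labelled with Cy3 and RNA from cells in 3, 6 or 9 mM caffeine labelled with Cy5, per the labels. No array had the dyes exchanged. The deposited values, made by the authors, were the log2 of a ratio of both channels: 2 to the power of each value was a ratio with 2 decimals (100% of values on each array, within a tolerance of 0.0001 after multiplication to whole hundredths), which fixes base 2. Per the deposited readme, scanner output in GenePix format exists for 5 of the arrays. Those scanner files were not analysed here, so signal over background was not examined. Background correction, spot filters, normalization and the sense of the ratio were not given in the sources used here. The array medians lay below 0, so the values had not been centred on the median. The labels did not say whether the untreated RNA of a strain was 1 pool for its 3 arrays, nor whether the doses were separate cultures. The p-values therefore measure only how far these arrays depart from a line in dose, which may be technical, and they leave out the spread of the untreated RNA.

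The table held 6214 probes. The platform's annotation gave 5596 of them a single gene symbol, 0 several, and did not list 618, which are unnamed here. All 5596 matched the symbol of a RefSeq gene of assembly R64 by Entrez identifier. Spots of the same gene were averaged (34 genes had at least 2 spots), giving 5561 genes. Between 22 (WT 9 mM) and 234 (mutant 6 mM) probes had no value on an array, and 5212 genes had a value on all 6. The lowest deposited ratio was 0.02 (WT 9 mM), where a step of the last decimal is large on the log scale. No coordinates are given, since the files name no genome build.

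Each array was centred on the median of its named genes. The model, chosen before the data were examined, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes): over all 6 arrays, a slope on dose in mM for each genotype and no intercept, because a log ratio against untreated RNA is 0 at 0 mM by construction. Residual degrees of freedom were 4 per gene, with 9.69 prior degrees of freedom. The WT slope, the mutant slope and mutant minus WT were tested 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The words rose and fell are used for genes called in this way, whether or not the value moved steadily with dose. Genes at least 2-fold from the array median were counted without a test. A dye bias of a gene that is the same on every array cancels in mutant minus WT at a matched dose, but not within a genotype.

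The 27 gene lists were fixed before the data were examined. They covered nitrogen catabolite repression, the retrograde response, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, Msn2/Msn4 stress, cell wall integrity, Gcn4 targets, multidrug resistance, hexose transport, gluconeogenesis, glycolysis, oxidative phosphorylation, phosphate starvation, the proteasome, chaperones, ergosterol, iron, autophagy, purines, G1 and DNA synthesis, histones, G2/M, both mating types, meiosis and the TOR complexes. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation. The estimated form also refers the test to the 4 residual degrees of freedom only. Calls were lost under it even where the estimate was near or below the preset (0.0107 for alpha-specific genes, -0.0065 for the G1 list). A call lost in this way therefore does not by itself show correlation within the list. In other called lists the estimate lay above the preset. It was 0.025 for nitrogen catabolite repression, 0.114 for the polymerases, 0.128 for ribosomal proteins and 0.146 for ribosome biogenesis. For general stress it was 0.147, for cell wall integrity 0.285 and for the retrograde response 0.295. If these estimates hold, the preset correlation makes the p-values of these lists too small. The list median on each array was also ranked among 10000 random lists of the same size, without matching on expression, since log ratios carry no level. With 3 matched doses, an exact sign-flip test of mutant against WT cannot go below p = 0.25 and was not used.

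The genes named in the text followed a rule fixed before the data were examined: the 12 highest and 12 lowest slopes in WT, 6 and 6 in the mutant, and 10 and 10 for the difference, among genes called with the same sign on all arrays concerned. TOR1 and TOR2 were always named, and for each list up to 4 measured members with the largest absolute WT slope. Exceptions are marked in the text as named after their values were seen.

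The procedure was tested on simulated data: 200 of 5212 genes were given known changes. For the WT slope, 18% of genes with a log2 change of 1 at 9 mM were called, 92% at a change of 2 and 100% at a change of 3, with 11 false calls. For the mutant slope the shares were 14%, 94% and 100%, with 8 false calls. For the difference they were 12%, 62% and 94%, with 3 false calls. These shares and false calls hold for the simulated values and are no error rate for the real arrays. The simulation gave no result on dye bias, shifts between arrays, correlation between genes, error in untreated RNA or departures from a line in dose.

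Alternatives fixed before the data were examined were the values as deposited, a mean over the doses in place of a slope, an intercept shared by all arrays, genes with values on at least 2 arrays of each genotype, robust eBayes, a threshold of 0.01, each genotype fitted by itself, matched doses as a block, each array left out in turn, an estimated correlation for the lists, and other fold thresholds. The fit with matched doses as a block tested the mean difference over the doses, not the slope. Alternatives added after seeing the data were the inclusion of unnamed probes, the 6 and 9 mM arrays alone, leaving out genes with a ratio below 0.10, the ASP3 copies as a single gene, and the shared intercept for the lists. Figures were drawn with matplotlib 3.10.9.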

Results

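Messenger RNA of budding yeast exposed to caffeine was compared with RNA of the same strain grown without it on 6 two-colour arrays. Caffeine is a methylxanthine that inhibits TOR complex 1, the kinase complex that ties growth to nitrogen supply. The strains were W303a laboratory yeast of mating type a, lacking the chromosomal TOR1 gene and carrying a plasmid with TOR1 tagged with the haemagglutinin epitope. The plasmid gene was either unaltered (called WT here) or carried the substitutions I1954V and W2176R (called mutant here). Each genotype was examined at 3, 6 and 9 mM caffeine, with 1 array per genotype and dose and therefore no replicate of any dose. The title of the series sets the caffeine response of the WT allele against that of the doubly substituted allele. On every array the labels put untreated RNA in the Cy3 channel and RNA from caffeine-treated cells in the Cy5 channel.

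The deposited values were log2 ratios, and 5212 named genes had a value on all 6 arrays. The sense of the ratio was not given in the sources used here. It was taken as caffeine over no caffeine, that is Cy5 over Cy3, the usual order for arrays of this kind, although the titles name the untreated sample first. If it ran the other way, every sign given here would turn. All values below were centred on the median named gene of the array. The deposited medians were -0.30, -0.36 and -0.38 in WT and -0.22, -0.40 and -0.54 in the mutant at 3, 6 and 9 mM, so a centred value lies above the deposited one by these amounts. The number of arrays limited the precision. Without replicates, each gene was fitted with a straight line in dose through 0 for each genotype. Its slope is given in log2 units per mM with its SE (n = 3 arrays per genotype). The SE was moderated by limma and pools the spread of both genotypes, so the WT and mutant slopes of a gene have the same SE.

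TOR1 itself showed no called response to caffeine. Its log2 ratios were -0.25, -0.06 and -0.06 in WT and 0.36, 0.24 and 0.37 in the mutant at the rising doses, with limma adjusted p = 0.817 and 0.355 for the slopes. TOR2, its paralogue, stood at -0.13, -0.10 and -0.91 in WT and -1.14, -1.20 and -0.44 in the mutant, with adjusted p = 0.243 and 0.0745. The mutant slope of TOR2 passed the test on the values as deposited (adjusted p = 0.0104) and without the mutant 9 mM array (adjusted p = 0.0299). As no array set the alleles against each other, these values could not check which strain was on which array.

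More genes departed from no change as the dose rose. In WT, 954 genes were at least 2-fold above or below the array median at 3 mM (499 higher, 455 lower), 1437 at 6 mM (738 and 699) and 1854 at 9 mM (902 and 952). In the mutant the counts were 669 at 3 mM (224 higher, 445 lower), 1309 at 6 mM (383 and 926) and 1478 at 9 mM (748 and 730). At 3 and 6 mM the mutant counts thus lay more on the lower side. With 1 array per dose, these counts had no test. Across genes, which are not independent replicates, the WT and mutant arrays of the same dose correlated with Pearson's r = 0.365 at 3 mM, 0.395 at 6 mM and 0.661 at 9 mM. Of the mutant arrays, that of 9 mM correlated most with each WT array, with r = 0.488 for WT 3 mM and 0.498 for WT 6 mM. At 9 mM, 441 genes were at least 2-fold higher in both genotypes, where independent lists would share 129.5, and 431 were at least 2-fold lower in both, where independent lists would share 133.3. A dye bias of a gene that is the same on every array could add to these correlations and shared genes.

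In WT cells with caffeine, 19 of 27 measured targets of nitrogen catabolite repression rose and 3 fell, 64 of 65 ribosome biogenesis genes fell, and 115 of 130 ribosomal protein genes fell. Camera called these 3 lists, but none of them with an estimated correlation (adjusted p = 0.0937 each). Among the steepest rises were those of the 4 near-identical copies of ASP3, the cell-wall asparaginase, and of DAL5, the allantoate permease. DAL5 rose by 0.81 ± 0.06 per mM and reached a log2 ratio of 6.19 at 9 mM (adjusted p = 5.41e-06). ALD6, the cytosolic aldehyde dehydrogenase that makes acetate, fell most steeply, at -0.54 ± 0.05 per mM, with -3.94 at 9 mM.

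Of 27 measured nitrogen catabolite repression targets, genes held down while a good nitrogen source is present, 19 rose, 3 fell and 5 did not pass the test (20 and 4 when adjusted over the list alone). The list median was 0.86, 2.05 and 2.64 at 3, 6 and 9 mM, and camera called the list higher (adjusted p = 9.25e-09). That call was lost with adjusted p = 0.0937 with an estimated correlation. ASP3-4 had a slope of 0.82 ± 0.07, ASP3-3 of 0.77 ± 0.05, ASP3-2 of 0.73 ± 0.09 and ASP3-1 of 0.68 ± 0.08. Spots for these copies could bind the same transcripts, so they may not be 4 separate measurements. DAL7, the malate synthase of allantoin breakdown, rose to 5.08 at 9 mM, CPS1, vacuolar carboxypeptidase S, to 4.53, and OPT2, an oligopeptide transporter, to 4.97. The 3 members that fell, named after their values were seen, were GAP1, the general amino acid permease (-1.87 at 9 mM), MEP3, an ammonium permease (-0.62), and GAT1, a transcriptional activator of this same pathway (-1.10).

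CHA1, the catabolic serine and threonine deaminase, reached 5.21 at 9 mM with a slope of 0.69 ± 0.07, and BAT2, the cytosolic branched-chain aminotransferase, stood at 4.15, 4.47 and 4.05. In the retrograde list, targets of Rtg1 and Rtg3 that feed glutamate synthesis when mitochondria fail, 4 of 8 genes rose, ATO3 fell and 3 did not pass (5 and 1 when adjusted over the list alone). The median of this list was highest at the lowest dose, with 1.60 at 3 mM against 1.08 and 1.13. CIT2, the peroxisomal citrate synthase, stood at 3.16, 4.58 and 3.62, and DLD3, a lactate dehydrogenase, at 3.79, 2.75 and 2.13. The list was called higher with adjusted p = 0.0316 and was not called, at adjusted p = 0.384, with an estimated correlation.

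Genes of ribosome production fell together in WT. Of 130 cytosolic ribosomal protein genes, 115 fell, none rose and 15 did not pass (121 fell when adjusted over the list alone), with medians of -0.93, -1.58 and -1.87. RPS0A reached -4.68 and RPL13A -3.94 at 9 mM, and many of these genes have a close duplicate whose transcript could bind the same spot. Among 65 ribosome biogenesis genes, 64 fell, by either adjustment, with medians of -1.13, -1.64 and -2.21. NSR1, the yeast nucleolin, had a slope of -0.51 ± 0.05, and the RNA helicases DBP2 and DRS1 both had -0.47, with SEs of 0.05 and 0.04. RNA polymerase I and III subunits fell in 14 of 18 cases (16 when adjusted over the list alone), RPA43 to -2.81 and RPC17 to -2.36 at 9 mM. The 3 lists were called lower with adjusted p = 1.45e-36, 1.20e-28 and 1.18e-06. None was called with an estimated correlation, which gave adjusted p = 0.0937 for ribosomal proteins, adjusted p = 0.0937 for ribosome biogenesis and adjusted p = 0.206 for the polymerases.

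Of 38 Msn2/Msn4 general stress genes 18 rose, none fell and 20 did not pass, by either adjustment, with medians of 0.28, 0.83 and 0.87 (adjusted p = 5.61e-07; adjusted p = 0.233 with an estimated correlation). TFS1, an inhibitor of carboxypeptidase Y, rose to 5.19, ALD3, a stress-induced aldehyde dehydrogenase, to 4.64, and HSP12, a small membrane-associated heat shock protein, to 4.38 at 9 mM. Of 25 cell wall integrity genes, the targets of the Slt2 kinase and Rlm1, 15 rose, 2 fell and 8 did not pass (17 and 2 when adjusted over the list alone). Their median was 1.12 already at 3 mM and 1.29 at 9 mM (adjusted p = 2.11e-05; adjusted p = 0.384 with an estimated correlation). PST1, a wall protein, stood at 3.03, 3.46 and 3.18, and the kinase gene SLT2 at 2.46, 2.09 and 2.13. The members that fell, named after their values were seen, were PIR1 and CIS3, structural wall proteins.

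Of 25 genes of G1 cyclins and DNA synthesis 9 fell, PCL2 rose and 15 did not pass, by either adjustment. Their median was -0.71 at 9 mM (adjusted p = 0.0317; adjusted p = 0.233 with an estimated correlation), and the call was also lost without the WT 6 mM array (adjusted p = 0.0637) or the WT 9 mM array (adjusted p = 0.0542). TOS4, a transcription factor of the G1/S transition, fell to -2.27 and RAD27, the flap endonuclease, to -1.94. Of 5 alpha-specific genes, markers of the other mating type, 3 rose, by either adjustment (STE3, the a-factor receptor, SAG1, alpha-agglutinin, and AFB1), and their median was 0.94, 1.26 and 1.15 (adjusted p = 0.0297; adjusted p = 0.233 with an estimated correlation). Genes specific to mating type a or to pheromone response gave 3 rises and 1 fall among 21, among them STE2, the alpha-factor receptor, at 2.11 and BAR1, the alpha-factor protease, at 1.87 at 9 mM.

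Further genes with steep falls in WT were RKI1, the ribose-5-phosphate isomerase, at -4.68, GNP1, a glutamine permease, at -3.46, AAH1, adenine deaminase, at -3.94, IMD4, an IMP dehydrogenase, at -3.68, INA1 at -3.68 and RBG1, a GTPase bound to ribosomes, at -5.27, all at 9 mM. Ratios this low were deposited with 2 decimals and are coarse.

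By limma, 1748 of 5212 genes were called in WT, 896 higher and 852 lower. On the values as deposited the split became 489 higher and 1483 lower, and the direction of each list called above stayed the same. Without the WT 3, 6 or 9 mM array 1529, 1226 and 1032 genes were called. When a dye bias constant for each gene was allowed through a shared intercept, 144 were called (over the 1748 genes, slopes were a median 0.807 and SEs a median 1.86 times those without it), and the retrograde (adjusted p = 0.509), cell wall (0.145), G1 (0.0711) and alpha-specific (0.150) lists were no longer called.

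**Figure D1:**
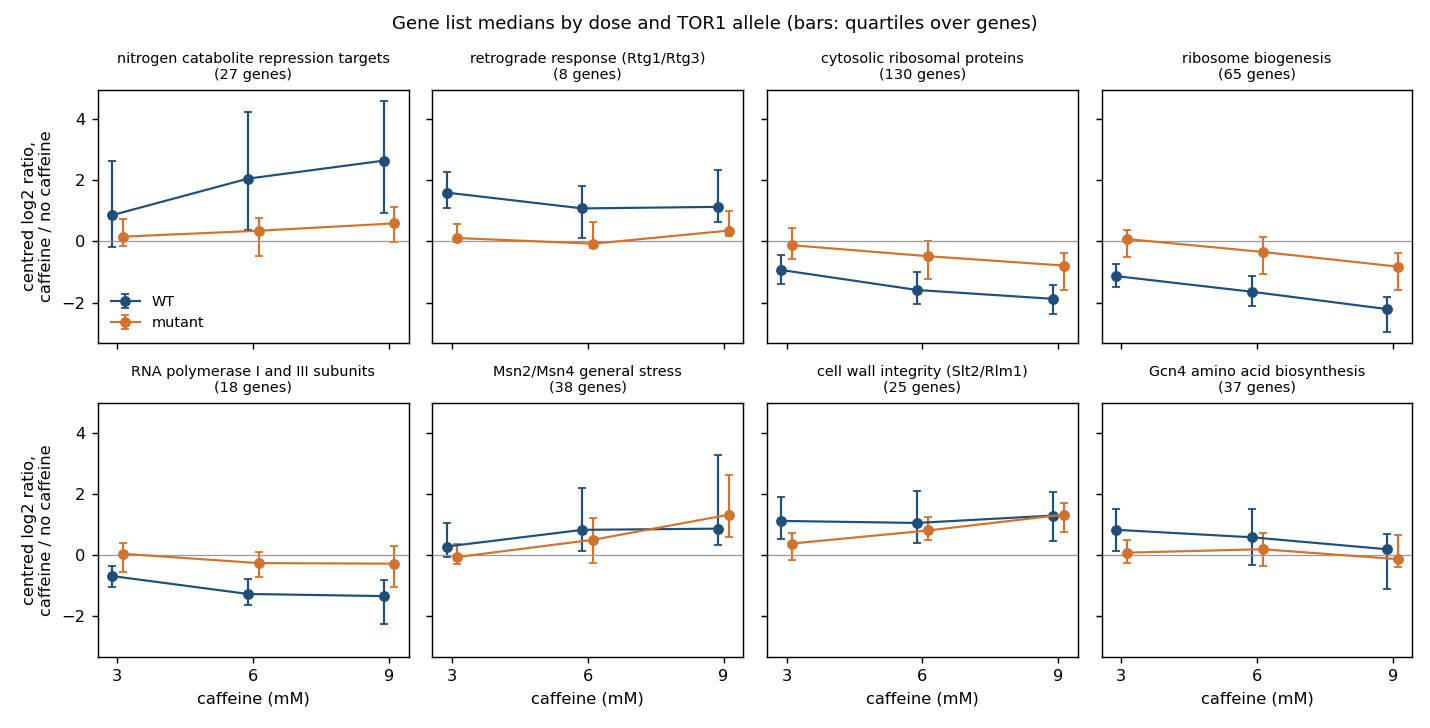
Median centred log2 ratio (caffeine over no caffeine, vertical axis) of 8 gene lists against caffeine dose in mM (horizontal axis), WT in blue and mutant in orange, 1 array per point, with bars from the lower to the upper quartile over the genes of the list. At 9 mM the nitrogen catabolite repression list had a median of 2.64 in WT and 0.59 in the mutant, ribosome biogenesis -2.21 and -0.82, and cell wall integrity 1.29 and 1.33.

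In mutant cells with caffeine, 16 of 38 general stress genes and 15 of 25 cell wall genes rose, and 50 of 130 ribosomal protein genes and 26 of 65 ribosome biogenesis genes fell. Camera called these 4 lists, but none of them with an estimated correlation (adjusted p = 0.536 each). HSP12 rose most steeply, at 0.61 ± 0.05 per mM, and reached 5.34 at 9 mM (adjusted p = 3.16e-05). LYS4, homoaconitase of lysine synthesis, fell most steeply, at -0.44 ± 0.04 per mM, and reached -3.52. The nitrogen catabolite repression list had medians of 0.16, 0.35 and 0.59 and was not called (adjusted p = 0.164), with medians above 82.7%, 96.0% and 99.5% of random lists of the same size.

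General stress genes rose in 16 of 38 cases, 2 fell (HSP42 and GLC3, named after their values were seen) and 20 did not pass (18 and 2 when adjusted over the list alone). Their median climbed from -0.06 at 3 mM to 0.50 at 6 mM and 1.33 at 9 mM (adjusted p = 7.94e-07; adjusted p = 0.536 with an estimated correlation). HSP26, a small heat shock chaperone, reached 4.94 and DDR2, a gene induced by many stresses, 4.37 at 9 mM. Of 25 cell wall genes 15 rose, none fell and 10 did not pass (17 and 1 when adjusted over the list alone), with medians of 0.38, 0.81 and 1.33 (adjusted p = 3.91e-05; adjusted p = 0.536 with an estimated correlation). SRL3 rose to 2.29, PST1 to 2.42 and SLT2 to 1.70 at 9 mM. ARO9 and ARO10, which begin the breakdown of aromatic amino acids, reached 4.81 and 4.37, and CHA1 reached 3.91.

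Ribosomal protein genes fell in 50 of 130 cases, RPL4B rose and 79 did not pass (55 and 1 when adjusted over the list alone). Their medians were -0.12, -0.48 and -0.79 (adjusted p = 2.08e-08; adjusted p = 0.536 with an estimated correlation), and RPL22A fell to -3.30 at 9 mM. Ribosome biogenesis genes fell in 26 of 65 cases, none rose and 39 did not pass (28 fell when adjusted over the list alone), with medians of 0.08, -0.34 and -0.82 (adjusted p = 2.68e-05; adjusted p = 0.536 with an estimated correlation). RPL4B was singled out after its values were seen. Without the mutant 9 mM array the calls of the biogenesis list (adjusted p = 0.165) and the stress list (adjusted p = 0.0671) ended.

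Of the nitrogen catabolite repression targets 6 of 27 rose, DAL80 fell and 20 did not pass (5 and 1 when adjusted over the list alone). DAL5 rose to 1.79 and ASP3-4 to 1.90 at 9 mM, and DAL80, a repressor of this pathway singled out after its values were seen, stood at -1.20. In the retrograde list, CIT1 and CIT2 rose among 8 genes (2 when adjusted over the list alone), to 2.93 and 2.15. Other steep falls were LYS9, saccharopine dehydrogenase of lysine synthesis, to -2.79, POC4, a proteasome assembly chaperone, to -3.30, SPL2, a regulator of phosphate transport, to -3.30, and GLY1, threonine aldolase, to -3.30. As in WT, ratios this low are coarse.

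By limma, 1455 of 5212 genes were called in the mutant, 633 higher and 822 lower. On the values as deposited the split became 201 higher and 1737 lower, and the median slope of the nitrogen list then lay at -0.01 per mM against 0.05 when centred. The count was 994 without the mutant 3 mM array, 584 without the mutant 6 mM array, 805 (156 higher, 649 lower) without the mutant 9 mM array and 22 with an intercept shared by all arrays (slopes a median 0.661 and SEs a median 1.85 times those without it), where the cell wall list was no longer called (adjusted p = 0.427). Of the calls, 361 genes rose and 387 fell in both genotypes, where independent lists would share 108.8 and 134.4, and 9 were called in opposite directions. A dye bias of a gene that is the same on every array would add to the shared calls.

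**Figure D2:**
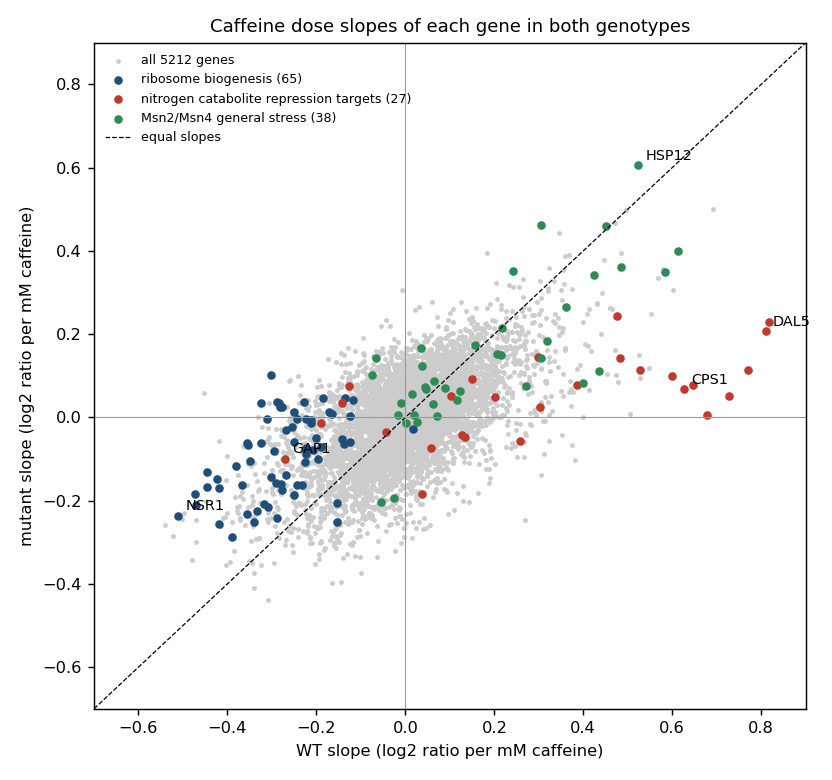
Slope of each of 5212 genes on caffeine dose in WT (horizontal axis) and in the mutant (vertical axis), in log2 ratio per mM, with 65 ribosome biogenesis genes in blue, 27 nitrogen catabolite repression targets in red and 38 general stress genes in green. The dashed line marks equal slopes. DAL5 lies at 0.81 and 0.21 and NSR1 at -0.51 and -0.24, both nearer 0 in the mutant, and HSP12 at 0.52 and 0.61.

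Slopes differed between the genotypes for 13 of 27 nitrogen catabolite repression targets, all lower in the mutant, and for 24 of 65 ribosome biogenesis and 15 of 130 ribosomal protein genes, all higher in the mutant. These lists were not called with an estimated correlation (adjusted p = 0.110, 0.187 and 0.187), and most of the 222 genes with a called difference lay outside them. OPT2 had a slope of 0.60 in WT and 0.10 in the mutant, a difference of -0.50 ± 0.06 per mM (adjusted p = 0.00153), and ASP3-3 differed by -0.66 ± 0.07 (adjusted p = 0.00153). IMD4, which fell to -3.68 in WT at 9 mM and stood at -0.62 in the mutant, differed by 0.51 ± 0.09 (adjusted p = 0.0116). In 3 of 3 doses the mutant value lay below WT for OPT2 and ASP3-3 and above it for IMD4. The naming rule required the same sign at all doses, so this agreement is no separate support. Stress and cell wall lists were not called as different. Their median differences, mutant minus WT, were still below 0 at 3 and 6 mM, with -0.29 and -0.38 for stress and -0.68 and -0.53 for the cell wall. Without the WT 9 mM array, 7 lists were called by genotype, 3 higher and 4 lower in the mutant, so the set of called lists depended on the arrays.

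Of the 27 nitrogen catabolite repression targets, 13 had a lower slope in the mutant, none a higher one and 14 did not pass (19 and 3 when adjusted over the list alone). The median difference, mutant minus WT, was -0.79, -1.90 and -2.02 at 3, 6 and 9 mM (adjusted p = 1.04e-10 for the slopes; adjusted p = 0.110 with an estimated correlation). At 9 mM, DAL5 stood at 6.19 in WT and 1.79 in the mutant, DAL7 at 5.08 and 0.14, and CPS1 at 4.53 and 1.26. The ASP3 copies stood between 4.64 (ASP3-1) and 6.27 (ASP3-3) in WT and between 0.71 (ASP3-1) and 1.90 (ASP3-4) in the mutant. VBA1, a vacuolar transporter of basic amino acids outside the list, stood at 4.19 and 0.27.

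Among ribosome biogenesis genes 24 of 65 had a higher slope in the mutant, none a lower one and 41 did not pass (36 when adjusted over the list alone), with median differences of 1.10, 1.30 and 1.54 (adjusted p = 4.14e-23; adjusted p = 0.187 with an estimated correlation). RRP36, a factor of early rRNA processing, stood at -2.02 in WT and 0.54 in the mutant at 9 mM, DBP8, an RNA helicase, at -2.27 and -0.13, and PWP2 and UTP13, members of the U3 small nucleolar ribonucleoprotein complex, at -2.21 and 0.54 and at -2.10 and 0.28. Ribosomal protein genes gave 15 of 130 with a higher slope in the mutant, none with a lower one and 115 not passing (55 when adjusted over the list alone), with median differences of 0.86, 0.85 and 1.19 (adjusted p = 4.14e-23; adjusted p = 0.187 with an estimated correlation). RPL14B stood at -2.18 in WT and 0.04 in the mutant at 9 mM. Of 18 RNA polymerase I and III subunits RPA12 and RPC37 passed, both higher in the mutant (10 when adjusted over the list alone; RPC37 was named after its values were seen). The median differences of that list were 0.65, 0.91 and 1.10 (adjusted p = 2.45e-06; adjusted p = 0.218 with an estimated correlation). With lines through 0, a called slope difference need not mean that the gap widened with dose. DBP8 stood at -2.88, -1.96 and -2.27 in WT. In the mutant it was highest at 3 mM, with 0.42 and -0.13 at 6 and 9 mM, so its gap was widest at 3 mM. RPA12 in the mutant stood at 0.81, 0.09 and 0.02. The median difference of each list here was larger at 9 mM than at 3 mM.

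Outside these lists, MUP1, a methionine permease, stood at -3.94 in WT and -0.79 in the mutant at 9 mM, BAP3, a branched-chain amino acid permease, at -2.10 and 0.79, BUD20, an export factor of the large ribosomal subunit, at -1.57 and 0.45, and KEL3 at -2.46 and 0.18. SRS2, a DNA helicase, moved in opposite directions, to 1.65 in WT and -2.30 in the mutant (difference -0.52 ± 0.07 per mM, adjusted p = 0.00299).

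General stress genes differed between genotypes in 1 case of 38, by either adjustment (UGA2, lower in the mutant, named after its value was seen), and cell wall genes in 0 of 25. The slopes of these lists were not called as different (adjusted p = 0.467 and 0.476), with median differences of -0.29, -0.38 and -0.06 for stress and -0.68, -0.53 and 0.01 for the cell wall at 3, 6 and 9 mM. The retrograde list gave -1.37, -0.79 and -0.66 and was not called as different (adjusted p = 0.284), with 0 of 8 genes called (1 higher and 2 lower when adjusted over the list alone). The alpha-specific list gave -0.77, -0.63 and -0.72 (adjusted p = 0.151), with 0 of 5 genes called (2 lower when adjusted over the list alone).

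By limma, 222 of 5212 genes had different slopes, 101 higher and 121 lower in the mutant, or 48 and 114 on the values as deposited. In 179 of them the mutant slope was nearer 0 than the WT slope. Of the 222, 88 rose in WT with a lower slope in the mutant, 96 fell in WT with a higher slope in the mutant, and 37 were called in the mutant but not in WT. The count was 19 (3 higher, 16 lower) without the WT 6 mM array, 138 (50 and 88) without WT 3 mM, 70 (16 and 54) without mutant 3 mM, 77 (25 and 52) without mutant 6 mM, 272 (72 and 200) without mutant 9 mM and 298 (136 and 162) without WT 9 mM. It was 255 (118 and 137) with a shared intercept and 10 (0 and 10) with 6 and 9 mM alone. Tests of the mean difference over the doses, not of the slope, gave 588 (270 and 318) with matched doses as a block and 194 (76 and 118) without the block. The count, and in part the split, thus depended on the arrays and the fit. Of the 20 genes named for this comparison, 14 were no longer called without WT 6 mM (adjusted p from 0.0506 for DAL5 to 0.152 for DBP8), and without a mutant array the calls of DBP8 (3, 6 or 9 mM; adjusted p = 0.0825, 0.0769 and 0.0502), BUD20 (3 mM; 0.0534), RPL14B (9 mM; 0.0612) and PWP2 (9 mM; 0.0577) ended.

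**Figure D3:**
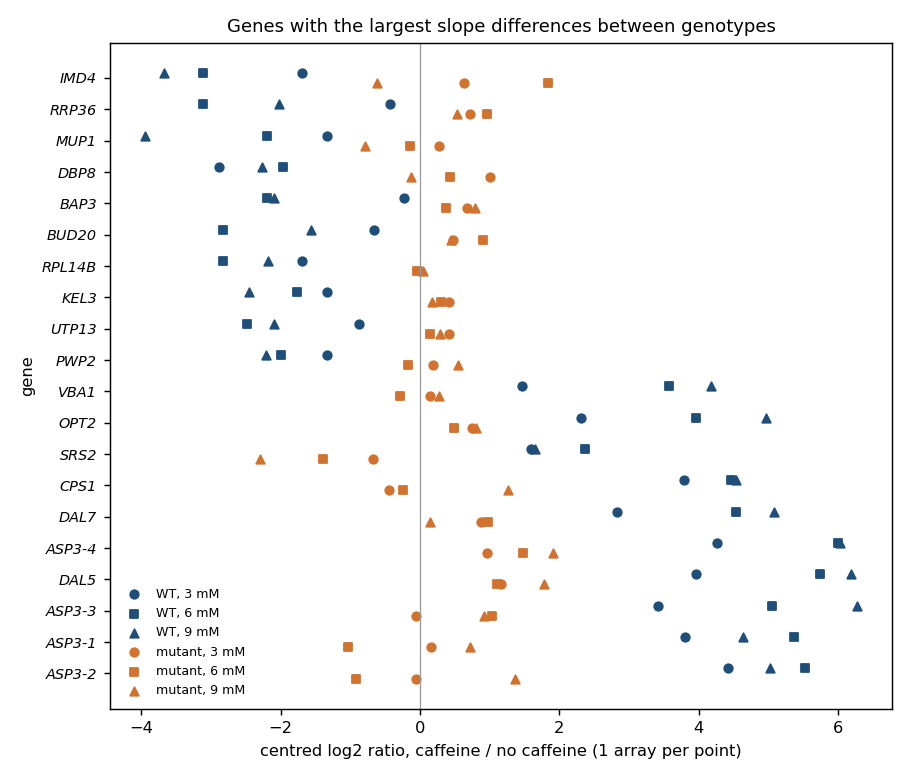
Centred log2 ratio (caffeine over no caffeine, horizontal axis) on each of the 6 arrays for the 20 genes with the largest called slope differences (vertical axis), 10 higher and 10 lower in the mutant, WT in blue and mutant in orange, with the dose given by the shape of the point. DAL5 lay between 3.96 and 6.19 in WT and between 1.10 and 1.79 in the mutant, and PWP2 between -2.21 and -1.33 in WT and between -0.17 and 0.54 in the mutant.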

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

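Of the tests reported here, the 2 counts over other splits of the arrays were planned, and the others (the size of the list differences at each dose, the ratio of slopes, the trends with dose, the ASP3 copies as 1 gene, the covariance of the 3 mM arrays and the reading of the shared intercept) were chosen after the result was seen.

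A difference between the genotypes, tested as mutant slope minus WT slope, was called for 222 genes. The 6 arrays can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. The real split, the 1 that gave as many, called 222 genes, and the highest of the others called 0. Each other split mixes both genotypes within a group, so a difference between them adds to the residual spread and lowers the calls. The contrast of 222 with 0 is therefore no support. For the gene lists the real split gave 4 called lists, 7 of the 10 splits gave at least as many, and the highest of the others gave 8.

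The same test singled out 4 lists by their median slope, mutant minus WT: nitrogen catabolite repression targets at -0.23 per mM, cytosolic ribosomal proteins at 0.15, ribosome biogenesis at 0.18 and RNA polymerase I and III subunits at 0.15. A dye bias constant for each gene cancels between genotypes at a matched dose, and the smallest median difference over the 4 lists and 3 doses was 0.65. With the near-identical ASP3 copies as 1 gene the nitrogen list stayed called at the preset correlation (adjusted p = 6.10e-08) and, as with 4 copies, not with an estimated correlation (adjusted p = 0.0809). A general attenuation in the mutant, from a lower effective caffeine dose or compressed arrays, stays open: on centred values the lowest ratio of mutant to WT slope in the stress and cell wall lists was 0.577 with any array left out, against 0.386 as the highest in the 4 lists, but on the values as deposited it was 0.106 against 0.531, and at 3 mM the stress and cell wall medians were lower in the mutant too (-0.06 against 0.28 and 0.38 against 1.12). A fixed difference between the untreated RNA of both strains stays open as well, as does a lower sensitivity of TOR signalling to caffeine with the substituted allele: the difference changed with dose by -0.14 per mM in the nitrogen list (95% interval over genes -0.24 to -0.03), 0.0442 in ribosome biogenesis (-0.003 to 0.09), 0.03 in ribosomal proteins (0.01 to 0.06) and 0.09 in the polymerases (-0.06 to 0.14), but with 1 array per dose such intervals leave out shifts between arrays, and they excluded 0 in 9 of the 27 lists, among them the stress (0.08) and cell wall (0.07) lists.

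In WT 33.5% of the genes were called and in the mutant 27.9%, without a dye exchange to separate caffeine from dye. A dye bias constant for each gene is argued against as the larger part of the log ratios at 9 mM, since the covariance across genes of both 3 mM arrays was at most 19.6% of the variance at 9 mM. This assumes that caffeine effects did not lower that covariance. At 3 mM the covariance was 30.4% of the variance in WT and 43.8% in the mutant, so the bound is weaker there. Whether it is the source of part of the calls stays open: with an intercept shared by all arrays 144 genes were called in WT, but the called genes kept a median 0.807 of their slope while the SE grew 1.86 times, so lost calls alone do not show a dye bias.

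Among data outside the comparisons, 136 of 541 probes without a gene name would be called in WT if they were included (40 higher, 96 lower), a smaller share than the 33.5% of named genes.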

How the results depend on the processing

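Alternatives added after seeing the data were the unnamed probes included, the 6 and 9 mM arrays alone, genes with a ratio under 0.10 left out, the ASP3 copies as 1 gene, and the shared intercept for lists. The counts were 1748 genes in WT, 1455 in the mutant and 222 for the difference, and 9, 4 and 4 lists. With an intercept shared by all arrays they were 144, 22 and 255 genes, at a threshold of 0.01 they were 1006, 522 and 11, and with the 6 and 9 mM arrays alone 1311, 828 and 10. Matched doses as a block gave 588 for the mean difference over the doses, of which 203 were among the 222. The mean difference without the block gave 194. Leaving out each array in turn gave 1032 to 1853 genes in WT, 584 to 1643 in the mutant and 19 (without WT 6 mM) to 298 for the difference. It gave 8 to 11 lists in WT, 2 (without mutant 9 mM) to 4 in the mutant and 4 to 7 (without WT 9 mM) by genotype. With an estimated correlation 0, 0 and 0 lists were called, and that form of the test also has only 4 degrees of freedom. All other alternatives stayed within 1.5 times these counts, but not always with the same genes. On the values as deposited, 1341 of the 1748 WT calls and 1023 of the 1455 mutant calls were kept. With a mean over the doses, 121 of the 222 difference calls were kept. A stricter threshold lowers the counts by construction, and with the shared intercept the SE of the called genes grew (median 1.86 times in WT, 1.85 in the mutant) while 95.1% and 92.6% kept the sign of their slope and 26.1% and 37.0% kept less than 50% of its size. For the other changes the cause was not tested. Of the difference calls, 1 was higher and 10 lower at 0.01, and 0 and 10 with 6 and 9 mM alone.

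Genes at least 1.5-fold from the median numbered 2180, 2659 and 3011 in WT and 2050, 2604 and 2826 in the mutant at 3, 6 and 9 mM, and at least 3-fold 250, 575 and 864 in WT and 69, 464 and 528 in the mutant. The slope of TOR1 in the mutant turned to -0.016 on the values as deposited, and that of TOR2 in WT to 0.0153 with the shared intercept, neither called. Of the genes named by their slopes, 10 in WT, 7 in the mutant and DBP8 for the difference lost their call with the shared intercept, all with the sign of the slope kept, and 13 for the difference lost it at 0.01 and 14 with 6 and 9 mM alone. The 7 in the mutant were CHA1 and all 6 named falls (limma adjusted p from 0.0667 for GLY1 to 0.325 for RPL22A). No named fall in the mutant thus stayed called with the shared intercept. With the shared intercept, the slope of CHA1 in the mutant shrank from 0.50 to 0.15 and that of BAT2 in WT from 0.60 to 0.21. Of the genes that lost their call, IMD4 in WT and GLY1 in the mutant had steeper slopes. DBP8 also lost its call on the values as deposited and MUP1 with a mean over the doses, and TOR2 in the mutant passed the test under both. The shared intercept ended the call of 4 lists in WT and 1 in the mutant, and called others in both. It called 7 lists in WT (2 higher, 5 lower), 5 of them also called without it, and 5 in the mutant, 3 of them also called without it. No other of the genes named by their slopes changed direction under the alternatives run for it. Leaving out genes with a ratio under 0.10 kept only 14 of 26 in WT, 8 of 14 in the mutant and 19 of 22 for the difference. Those left out were all 12 named falls in WT, all 6 in the mutant, and IMD4, RRP36 and MUP1 for the difference. This check therefore tested no named fall within a genotype. No called list changed direction on the values as deposited, with a mean over the doses, a shared intercept, the ASP3 copies as 1 gene or any array left out, and apart from the estimated correlation the lists were run with no other alternative. None of these were run for the other genes in the text. The number of arrays limits these results, and signal over background was not examined.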

Other observations

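The genes called in opposite directions in both genotypes, and CPA1, GCN4, IMD3 and the further members named here outside the rule, were chosen after their values were seen, and no explanation was tested for them. Counts in brackets are rises and falls adjusted over the list alone, followed by the adjusted p of the list from camera. None of the lists was called in the comparison for which it is given here.

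Of the 9 genes called in opposite directions, SRS2, a DNA helicase, IRC4, NIT1, YAL065C and YLR460C rose in WT and fell in the mutant, and MTC1, OAC1, a mitochondrial carrier of oxaloacetate and sulfate, SUL2, a sulfate permease, and YBL081W fell in WT and rose in the mutant. At 9 mM, OAC1 stood at -1.02 in WT and 1.15 in the mutant, MTC1 at -1.31 and 1.23, and YLR460C at 2.02 and -1.30. All 9 also passed the test of the difference, with adjusted p from 0.00299 (SRS2) to 0.0408 (YBL081W).

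Genes of amino acid and purine synthesis went both ways. Of 37 Gcn4 targets, 10 rose and 8 fell in WT (14 and 9; list adjusted p = 0.424), with medians of 0.83, 0.59 and 0.19 at 3, 6 and 9 mM, and 5 rose and 5 fell in the mutant (5 and 5; 0.724), with 3 higher and 1 lower in the mutant for the difference (3 and 1; 0.543). The median difference of this list, mutant minus WT, was -1.16, -0.66 and 0.06 at 3, 6 and 9 mM. Its change with dose, 0.18 per mM (95% interval over genes 0.10 to 0.25), was the largest of the 27 lists. With 1 array per dose, that interval leaves out shifts between arrays. SNZ1, of vitamin B6 synthesis, stood at 4.22, 3.98 and 2.53 in WT. GCN4, the activator itself, fell in the mutant to -2.65 at 9 mM against -0.91 in WT (difference adjusted p = 0.0371), and CPA1, a subunit of carbamoyl phosphate synthetase, stood at 1.61 against -0.94 (0.0483). Of 17 purine genes, 11 rose in WT and ADE8, IMD2, IMD3 and IMD4 fell (12 and 4; 0.116), and 3 rose and ADE8 fell in the mutant (3 and 1; 0.219). The 3 IMD genes, which encode IMP dehydrogenase, had higher slopes in the mutant and ADE17 a lower one (3 and 1; 0.699). GCV2, of glycine cleavage, rose to 3.09 in WT.

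In WT 8 of 18 autophagy genes rose (8 and 1; 0.0610), among them ATG8, which coats the autophagosome, to 1.12 at 9 mM, against 4 rises and 2 falls in the mutant (5 and 2; 0.233) and 0 differences (0 and 0; 0.4996). Of 21 G2/M and M/G1 genes 2 rose and 8 fell in WT (2 and 9; 0.116) and 3 rose and 8 fell in the mutant (4 and 10; 0.1601), with 0 differences (0 and 0; 0.836). CLB1, a mitotic cyclin, fell to -3.94 in WT and -2.30 in the mutant. Of 9 core histone genes 4 fell in each genotype (0 and 4; 0.151 in WT, 0 and 6; 0.1601 in the mutant), with 0 differences (0 and 0; 0.681). In the G1 list the mutant had 2 rises and 7 falls (2 and 8; 0.608), with POL1 higher for the difference (1 and 0; 0.284). Chaperones gave 1 rise and 5 falls in WT (1 and 5; 0.126), 1 and 4 in the mutant (1 and 4; 0.834) and 0 differences (0 and 0; 0.240), and proteasome genes 3 and 1 (1 and 0; 0.687), 3 and 4 (2 and 3; 0.834) and SCL1 lower for the difference (0 and 1; 0.4996).

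In carbon metabolism, MLS1, malate synthase, was the 1 of 15 gluconeogenic and glyoxylate genes that rose in WT (1 and 0; 0.244), to 3.13 against 0.67 in the mutant (difference adjusted p = 0.0126; list 0 and 1, 0.467), and FBP1 was the 1 that rose in the mutant (0 and 0; 0.709). Of 16 glycolytic genes, HXK2 and CDC19 fell in WT (0 and 2; 0.904), 5 rose and 2 fell in the mutant (5 and 3; 0.219), and 0 differed (0 and 0; 0.151). Hexose transporters gave 3 rises and 3 falls of 15 in WT (4 and 4; 0.891), 2 and 1 in the mutant (2 and 1; 0.657) and 0 differences (0 and 0; 0.684). Oxidative phosphorylation gave 5 and 1 of 34 in WT (4 and 1; 0.330), 7 and 2 in the mutant (8 and 2; 0.203) and RIP1 lower for the difference (0 and 1; 0.681).

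Phosphate genes gave 4 rises and 1 fall of 16 in WT (4 and 1; 0.244) and 1 and 4 in the mutant (1 and 4; 0.724), and PHO12, SPL2 and GIT1, the glycerophosphoinositol permease, were lower for the difference (0 and 4; 0.0602), GIT1 at 3.31 in WT and 1.02 in the mutant at 9 mM. The iron regulon gave 6 and 4 of 19 in WT (6 and 5; 0.519), 2 and 5 in the mutant (2 and 6; 0.834) and 0 differences (0 and 0; 0.312). Multidrug resistance genes gave 3 and 2 of 16 in WT (3 and 2; 0.636), 2 and 5 in the mutant (3 and 5; 0.797) and RTA1 lower for the difference (0 and 2; 0.362). Ergosterol genes gave 1 and 0 of 24 in WT (1 and 0; 0.689), 5 and 3 in the mutant (6 and 5; 0.625) and ERG27 lower for the difference (2 and 4; 0.699).

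Genes of mating type a and pheromone response, with 3 rises and 1 fall in WT (3 and 1; 0.768), gave 1 and 2 of 21 in the mutant (1 and 2; 0.834) and 0 differences (0 and 0; 0.617). Meiotic genes gave 2 and 0 of 16 in WT (1 and 0; 0.276), 4 and 2 in the mutant (4 and 2; 0.657) and DIT2 lower for the difference (0 and 1; 0.681). Among 12 TOR complex subunits, KOG1, the regulatory subunit of TOR complex 1, fell in both genotypes, to -1.36 in WT and -1.94 in the mutant, TSC11 rose in both, and in the mutant AVO2 rose and TCO89 fell (WT 0 and 1; 0.687, mutant 2 and 5; 0.834), with 0 differences (0 and 0; 0.830). In the mutant AFB1 alone of the 5 alpha-specific genes rose (1 and 0; 0.525), CIT1 and CIT2 rose in the retrograde list (2 and 0; 0.322), and RPA43, RPA34, RPC25 and RPC17 fell among the polymerase subunits (0 and 4; 0.425).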
